A study of Mus musculus with 12 samples.

How the data were processed

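Bulk RNA sequencing of mouse B cell precursors was analysed from 1 deposited table with 47069 Ensembl genes and 12 libraries, in 4 groups of 3. Per the labels, total RNA was isolated with the Quick-RNA MicroPrep kit, and Novogene is named beside it as the company. The values are FPKM that the authors computed before the table was deposited. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and the tools were HISAT2, HTSeq and Cufflinks. The step each tool was used for, their versions and settings are not given in the sources used here. The gene lengths behind the deposited FPKM are not given in the sources used here either. No column of values per sample was left out (0 columns). Of the gene IDs, 46488 (98.8%) are in GENCODE M21, which supplied symbols, gene types and coordinates on GRCm38.

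Within a gene, the deposited FPKM of all libraries are whole multiples of 1 step per library, so the counted fragments were recovered from these steps. Whole fragments were recovered for 25186 genes and failed for 0, and 100% of the values were rebuilt from them within a relative tolerance of 1e-08. A further 18793 genes stood at 0 in every library and 3090 were above 0 in 1 library. In a test on 6000 simulated genes the recovery returned 99.93% exactly, and 100% up to a common divisor. The implied gene length was within 1% of the exon union of M21 for 34.7% of the genes, so most lengths were not those of M21 exon unions. Totals of counted fragments ran from 31.9 M to 49.8 M per library, a ratio of 1.56 between the highest and the lowest. FPKM divides by library totals, so depth enters the fits through the spread of low genes.

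Tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Each comparison was fitted with limma (lmFit, eBayes with trend) on log2(FPKM + 1), 2-sided. Genes with at least 1 FPKM in at least 3 of the libraries of the fit were tested, and a Benjamini-Hochberg adjusted p under 0.05 counted as a call. The β-catenin group was compared with the sorted controls, the inhibitor group with the untreated group and the sorted controls with the untreated group, each in a fit of those 6 libraries. The difference of both effects was a contrast in a 4-group model of all 12 libraries. Overlap was counted among genes tested in both comparisons, with Fisher's exact test across genes. Standard errors are those of limma.

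Lists of genes were fixed before the data were examined: 25 for processes and 9 for cell types, tested with camera at a correlation of 0.01 where at least 5 members were tested, and adjusted over the lists of a comparison. Estimated correlations and fry served as alternatives. Members called over all genes were counted, and again adjusted over the list alone. Summed FPKM of a list includes members too low to test. Genes were named by a rule fixed in advance. It took the 10 highest and 10 lowest log2 fold changes of each main comparison (5 for the others) among called protein coding genes with a usual symbol, no antigen receptor segment and no overlap between groups. It added Ctnnb1, Gsk3a, Gsk3b, Axin2, Lef1, Tcf7 and Myc, and up to 4 members per list with the largest changes. Other genes named in the text were chosen after their values were seen, and some results under the rule are not reported here.

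Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, centring on the median, robust eBayes, all 12 libraries in the fit, the library number as a block, and leaving out each library in turn. Alternatives added after the data were seen were voom on the recovered fragments, leaving out both libraries numbered 249, leaving out library 244 together with both unsorted libraries numbered 249, and the list tests without these libraries, with voom and under other scalings. Whether the numbers pair libraries was checked by correlating deviations from the group mean over the 12685 tested genes. Between untreated and inhibitor libraries the r was 0.609 for number 242, 0.77 for 249 and 0.36 for 251, each above the fixed threshold of 0.1 and above every other number, so these numbers pair libraries.

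The calls were tested on simulated data with the same depths and spread, but with fewer changed genes. In the β-catenin comparison 65, 63 and 65 genes changed 1.5-, 2- and 4-fold were tested. Another 10 lists of 25 genes were shifted by 0.5 on the log2 scale, whereas 4656 genes were called in the real libraries. The adjusted p depends on the share of changed genes, so the rates given next need not hold there. Of genes changed 1.5-, 2- and 4-fold, limma called 18.5%, 46% and 83.1% in the β-catenin comparison, with 7 false calls among 12411 unchanged genes. In the inhibitor comparison it called 8.96%, 35.4% and 72.3% (6 false calls of 12309), in the difference of effects 3.08%, 22.7% and 59.1% (8 of 13336) and between the control groups 29.2%, 57.1% and 77.3% (16 of 12149). Camera called 10 of 10 shifted lists in each comparison. It called 2 of 100 unshifted lists in the β-catenin comparison and 0 of 100 in the others. With an estimated correlation it called 8 of 10 shifted lists in the inhibitor comparison, 10 of 10 in each other comparison, and 0 of 100 unshifted lists in each. Each simulated gene was drawn independently of the others, so these rates need not hold for lists whose genes vary together. Other splits of the real libraries called up to 19 lists in the β-catenin and 20 in the inhibitor comparison.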

Results

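RNA sequencing of bulk cells gave expression values for 47069 Ensembl genes in 12 libraries of mouse B cell precursors, the dividing cells of the B lineage that are still assembling their immunoglobulin genes. The precursors came from cultures of hematopoietic stem cells in Iscove's medium with IL7, the cytokine on which mouse B cell precursors depend. The libraries form 4 groups of 3. The sorted control group (numbers 242, 249 and 251) and the β-catenin group (numbers 244, 255 and 262) were sorted on B220, a form of the surface phosphatase CD45 carried by B lineage cells. In the β-catenin group the Mb1-Cre recombinase, active from the earliest B lineage stages, removes exon 3 of Ctnnb1, the exon with the phosphorylation sites through which the kinase GSK3 marks β-catenin for destruction, so that the protein is stabilised. The sample titles call these libraries KO and the sorted controls WT, and do not say whether the controls carry Mb1-Cre. The untreated and the inhibitor groups are unsorted wildtype cultures numbered 242, 249 and 251, kept overnight without or with 40 nM LY2090314, a small molecule that inhibits GSK3. The values are FPKM, from which the counted fragments could be recovered. The sorted control libraries held 49.6, 41.6 and 31.9 M counted fragments in the order of their numbers. The β-catenin libraries held 47.0, 49.8 and 33.5 M, the untreated libraries 42.3, 42.7 and 37.3 M, and the inhibitor libraries 48.1, 38.0 and 38.5 M. No library pair of 1 group agreed within sampling noise, since the lowest mean chi-square per gene of a pair was 19.6 (sorted controls 249 and 251). The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between these samples.

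Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507 of GRCm38) stood at 284, 266 and 237 FPKM in the sorted controls and at 228, 331 and 282 in the β-catenin libraries 244, 255 and 262. It stood at 250.4, 258 and 230.5 FPKM in the untreated and at 234, 241 and 225 in the inhibitor libraries. A value per gene cannot show the loss of 1 exon, so these levels check nothing about the genotype. Some single libraries stood apart, and this is given again beside the gene groups concerned. Library 244 of the β-catenin group held little B lineage RNA, with Cd79b, a signalling chain of the B cell receptor, at 5.36 FPKM against 72.2 in library 255, 81.6 in library 262 and 502 ± 89.4 in the controls. The same library had both Xist, which is transcribed from the inactive X chromosome of female cells (169 FPKM), and the Y-linked gene Ddx3y (19.5 FPKM), whereas every other library had 1 of the 2 at less than 1 FPKM. Both unsorted libraries numbered 249 carried abundant myeloid transcripts, with the granule enzyme Lyz2 at 2317 and 2908 FPKM against at most 131 in the other unsorted libraries.

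**Figure D1:**
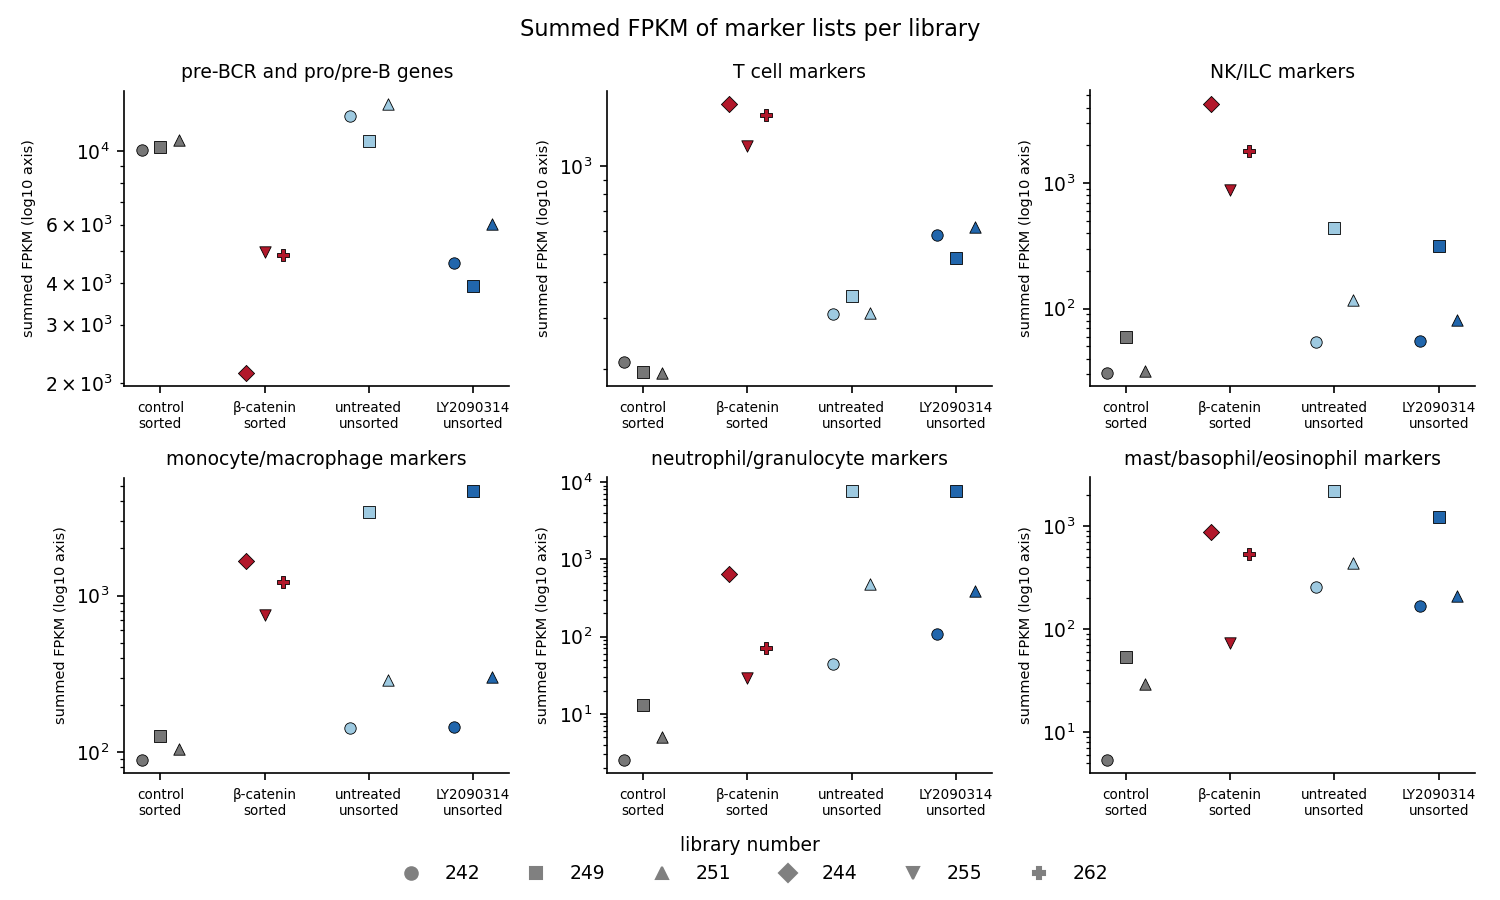
Summed FPKM (log10 axes) of the genes of 6 lists in each of the 12 libraries, with 1 symbol per library number and 1 colour per group. Library 244 had the lowest sum of pre-BCR and pro/pre-B genes (2152) and the highest sum of NK/ILC markers (4276), and the unsorted libraries numbered 249 had the highest sums of neutrophil markers (7664 and 7575).

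The first comparison asked how stabilised β-catenin changes the transcriptome of B220-sorted precursors. Axin2, Nkd1, Apcdd1 and Rnf43 of the WNT pathway rose, while Cd22, Blk, Cd79b, Spib and some other genes of B cell precursors fell. Transcripts of T cells and of NK and innate lymphoid cells (ILC) rose from low levels. Many genes of DNA replication and ribosome assembly and some of mitosis fell by smaller amounts. The transcription factor Tcf7 (TCF-1), a nuclear partner of β-catenin that also drives T cell development, rose from 3.83 ± 0.332 to 464 ± 66.9 FPKM (mean ± SD, n = 3; log2FC 6.58 ± 0.129 SE, adjusted p = 3.73e-05). Here log2FC is the difference of group means of log2(FPKM + 1), a scale that understates the change of low genes. With limma, 2387 genes were higher and 2269 lower of 12813 tested. At least 2-fold changes were seen in 1266 of the higher and 706 of the lower genes. Without library 244, 2386 genes were higher and 2616 lower, and 3970 of the 4656 genes called with all libraries were called again. There 12202 genes were tested, and a gene below 1 FPKM in every sorted control could not pass the filter. Untested genes count among those not called again.

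Of the list of WNT target genes, 10 of 16 tested members rose, 2 fell and 4 were not called (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0196, or 0.469 with an estimated correlation). Without library 244 the list was not called (6 higher and 3 lower of 12 tested, camera adjusted p = 0.0968). Genes below 1 FPKM in every sorted control cannot pass the filter without it, so Apcdd1 and Rnf43 were not among the 12. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a scaffold of the β-catenin destruction complex and a feedback target, rose from 5.12 ± 1.72 to 36.5 ± 17.6 FPKM (log2FC 2.53 ± 0.406 SE, adjusted p = 0.0076). Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014) is in the list too. The WNT inhibitor gene Apcdd1 rose from 0.181 ± 0.171 to 39.7 ± 31.8 FPKM (log2FC 4.67, adjusted p = 0.00716). Rnf43, a ubiquitin ligase for WNT receptors, rose from 0.11 ± 0.0885 to 20.3 ± 10.8 (log2FC 4.13, adjusted p = 0.00218) and the feedback inhibitor Nkd1 from 1.52 ± 0.631 to 40.7 ± 31.8 (log2FC 3.66, adjusted p = 0.0137). Myc fell (log2FC -1.03 ± 0.291 SE, adjusted p = 0.0372). Its call was lost without the filter (adjusted p = 0.0749) and without sorted control 242 (0.12), sorted control 251 (0.128), library 255 (0.0783) or library 262 (0.115). The spread between libraries was too large to call Lef1, another nuclear partner of β-catenin (log2FC -1.33, adjusted p = 0.201). Ctnnb1 itself (log2FC 0.08, adjusted p = 0.7) and Gsk3b (log2FC 0.05, adjusted p = 0.75) were not called. Gsk3a was slightly higher (log2FC 0.30, adjusted p = 0.0191). It was not called under median centring (adjusted p = 0.0678) or without sorted control 242 (0.0772), sorted control 249 (0.0714), sorted control 251 (0.0717) or library 262 (0.0704). Of the pathway's receptors, ligand carriers and cofactors, 2 of 24 tested members rose, 6 fell and 16 were not called (camera adjusted p = 0.396). The cofactor Bcl9 fell (log2FC -1.22, adjusted p = 0.00737) and the corepressor Tle3 rose (log2FC 0.50, adjusted p = 0.00948).

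**Figure D2:**
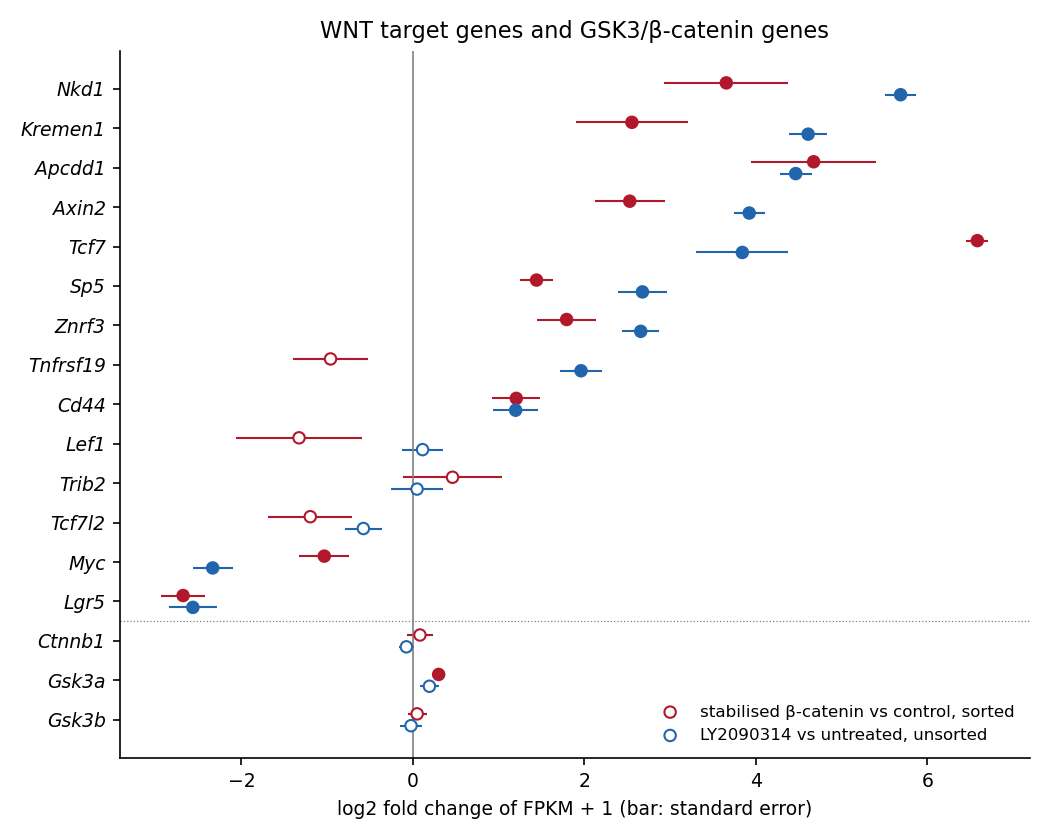
Log2 fold change of FPKM + 1 with its standard error for the tested WNT target genes and, under the dotted line, Ctnnb1, Gsk3a and Gsk3b, in the sorted comparison (red) and in the inhibitor comparison (blue), with filled circles for adjusted p under 0.05. Nkd1, Apcdd1, Axin2 and Tcf7 were higher in both comparisons and Myc was lower in both, while Ctnnb1 and Gsk3b lay within 0.1 of 0.

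Of the genes that define the B lineage some fell, some rose and many were not called, with a wide spread between the β-catenin libraries. Spib, an ETS family factor of B cells, fell from 563 ± 87.8 to 42.8 ± 38.9 FPKM (log2FC -4.57 ± 1.14 SE, adjusted p = 0.0267). It had 2.45 FPKM in library 244 against 46 and 80 in libraries 255 and 262. Of the B lineage transcription factors, 4 of 26 tested members rose, 9 fell and 13 were not called (5 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.0376, or 0.682 with an estimated correlation). Quantile normalization ended the list call (camera adjusted p = 0.134), as did median centring (0.114). Bcl11a (log2FC -3.36, adjusted p = 0.0194) and Spi1 (PU.1; log2FC -1.91, adjusted p = 0.0213) were among those that fell, and the stem cell and erythroid cofactor Lmo2 rose (log2FC 2.10, adjusted p = 0.0453). Pax5, which holds cells in the B lineage, had 82.6 ± 70.5 against 543 ± 72.9 FPKM and was not called (log2FC -3.62, adjusted p = 0.058). Of the pre-BCR and pro/pre-B genes, 4 of 28 tested members rose, 7 fell and 17 were not called (4 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0523). Without library 244 the counts were 6 higher and 17 lower of 28 tested (camera adjusted p = 0.00282, or 0.522 with an estimated correlation). The inhibitory receptor Cd22 fell from 61.8 ± 28.4 to 1.28 ± 1.08 FPKM (log2FC -4.80 ± 0.512 SE, adjusted p = 0.00282). The kinase Blk fell from 252 ± 14.3 to 23.4 ± 20.4 (log2FC -4.14, adjusted p = 0.0268) and Cd79b from 502 ± 89.4 to 53 ± 41.6 (log2FC -3.88, adjusted p = 0.0276). Vpreb2, part of the surrogate light chain, fell from 1294 ± 100.3 to 118 ± 96.9 FPKM (log2FC -4.43, adjusted p = 0.0377), but it is nearly identical to Vpreb1, so the split of reads between both is uncertain. The largest falls included the Fc receptor-like gene Fcrla (log2FC -5.31 ± 0.631 SE, adjusted p = 0.0036) and endoglin (Eng, log2FC -4.59, adjusted p = 0.00392). Crhbp (log2FC -3.96, adjusted p = 0.0119), the sialic acid receptor Siglecg (log2FC -3.95, adjusted p = 0.0143) and the protease Tmprss3 (log2FC -3.92, adjusted p = 0.0039) fell too. Several of these calls needed all 3 sorted controls. Spib was not called without the filter (adjusted p = 0.0569) or without sorted control 242 (0.0814), 249 (0.0892) or 251 (0.0926). Blk was not called without the filter (0.057) or without sorted control 242 (0.0836), 249 (0.0872) or 251 (0.0929). Vpreb2 was not called without the filter (0.0774), sorted control 242 (0.108), 249 (0.105) or 251 (0.119), or library 262 (0.0574). Crhbp was lost without sorted control 249 (0.0506) or 251 (0.0571), and Siglecg without 249 (0.0601) or 251 (0.0633).

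Other stages of the B lineage went both ways. Of 12 V(D)J recombination genes, 2 fell, the chromatin proteins Hmgb1 and Hmgb2 (camera adjusted p = 0.248). Of the immature and mature B cell genes, 6 of 24 tested members rose, 5 fell and 13 were not called (camera adjusted p = 0.905). The BAFF receptor gene Tnfrsf13c fell (log2FC -3.32, adjusted p = 0.00693) and the MHC class II gene H2-Eb1 rose (log2FC 3.25, adjusted p = 0.0157). Plasma cell genes also went both ways (5 higher and 4 lower of 16 tested; camera adjusted p = 0.905). Prdm1 (Blimp-1), the regulator of plasma cells, rose from 0.43 ± 0.102 to 22.5 ± 9.76 FPKM (log2FC 3.94, adjusted p = 0.00183).

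T lineage and NK/ILC transcripts rose together with those of other lineages. Gzma, a granzyme of cytotoxic lymphocytes, rose from 0.852 ± 0.61 to 245 ± 91.3 FPKM (log2FC 7.03 ± 0.341 SE, adjusted p = 0.000328). Of the NK/ILC markers, 14 of 15 tested members rose and 1 was not called (15 higher adjusted over the list alone; camera adjusted p = 1.26e-08, or 0.469 with an estimated correlation). The IL2 receptor chain Il2rb (log2FC 5.71, adjusted p = 0.00286), the lectin receptor chain Klrd1 (log2FC 5.43, adjusted p = 0.00332) and Gzmb (log2FC 5.25, adjusted p = 0.00454) were among them. Their summed FPKM was 4276, 883 and 1805 in libraries 244, 255 and 262, and 40.7 ± 16.3 in the controls. Of the T cell markers, 10 of 13 tested members rose and 3 were not called (10 higher adjusted over the list alone; camera adjusted p = 1.96e-07, or 0.181 with an estimated correlation). Cd8b1 rose from 0.0195 ± 0.0213 to 43.8 ± 16.5 FPKM (log2FC 5.39, adjusted p = 0.000386) and the T cell receptor kinase Zap70 from 1.13 ± 0.28 to 59.5 ± 4.54 (log2FC 4.83, adjusted p = 4.58e-05). The CD3 chain Cd3g rose from 6.72 ± 3.83 to 270.5 ± 267 FPKM (log2FC 4.71, adjusted p = 0.00913), with 572 in library 244. The wider Notch and T lineage list, which shares some of these genes, behaved alike (18 higher and 2 lower of 24 tested; camera adjusted p = 5.45e-08, or 0.181 with an estimated correlation). It includes Cd7, a T cell surface gene (log2FC 5.86, adjusted p = 0.00281). Without library 244, 9 of 10 tested NK/ILC markers (camera adjusted p = 5.71e-07, or 0.634 with an estimated correlation) and 5 of 7 tested T cell markers (camera adjusted p = 0.000678, or 0.522 with an estimated correlation) rose. Other genes with the largest rises were the adhesion receptor Adgrg5 (log2FC 6.46, adjusted p = 4.58e-05), the protease inhibitor Serpine2 (log2FC 6.22, adjusted p = 0.00147), and the adenylate kinase Ak8 (log2FC 6.06, adjusted p = 0.00284, but 0.0853 with voom). The troponin Tnni1 (log2FC 5.90, adjusted p = 0.000452), the lymphocyte membrane gene Ms4a4b (log2FC 5.83, adjusted p = 0.00275) and the receptor phosphatase Ptprf (log2FC 5.76, adjusted p = 0.00321) followed.

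Markers of further lineages were higher in the β-catenin libraries too. Of the monocyte and macrophage markers, 7 of 11 tested members rose, 1 fell and 3 were not called (camera adjusted p = 0.00153, or 0.469 with an estimated correlation). Ly6c2 led (log2FC 6.03, adjusted p = 0.00151), followed by Fcer1g (log2FC 5.75, adjusted p = 0.000328) and Tyrobp (log2FC 5.24, adjusted p = 0.00251), adaptor chains that NK cells also use. Of the dendritic cell markers, 5 of 7 tested members rose and 2 were not called (camera adjusted p = 0.00083, or 0.469 with an estimated correlation). They included the integrin Itgax (log2FC 5.02, adjusted p = 0.00298) and Klrb1b (log2FC 4.95, adjusted p = 0.00493), a lectin receptor known from NK cells. Of the mast, basophil and eosinophil markers, 3 of 10 tested members rose and 7 were not called (camera adjusted p = 0.0113, or 0.577 with an estimated correlation). Of the neutrophil markers, 3 of 7 tested members rose and 4 were not called (camera adjusted p = 0.0204, or 0.469 with an estimated correlation). Without library 244 the mast cell list was not called (camera adjusted p = 0.132) and fewer than 5 members of the neutrophil and dendritic lists were left to test. Members below 1 FPKM in every sorted control cannot pass the filter there. Of the stem and progenitor markers, 5 of 9 tested members rose and 4 were not called (camera adjusted p = 0.0492, or 0.469 with an estimated correlation; 0.059 with voom), and the receptor Kit was the highest of them (log2FC 3.81, adjusted p = 0.00353). Fewer than 5 erythroid and megakaryocyte markers were tested, and their summed FPKM was 346 ± 222 against 142 ± 30.3. The stromal list, also below 5 tested genes, rested on Thy1, which T cells share, at 476 ± 68 against 69 ± 12.4 FPKM (log2FC 2.77, adjusted p = 0.000558).

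Lists of proliferation and growth held more falls than rises, except for cyclins and CDK inhibitors. These changes came from the libraries in which the summed FPKM of NK/ILC markers was 2321 ± 1754 against 40.7 ± 16.3, that of T cell markers 1440.0 ± 239 against 201 ± 9.19 and that of pre-BCR and pro/pre-B genes 3984 ± 1587 against 10370.0 ± 388. Without library 244, which had both Xist and Y-linked transcripts, the counts were 0 higher and 20 lower of 32 tested for G1/S, 0 higher and 14 lower of 30 tested for G2/M and 0 higher and 28 lower of 36 tested for ribosome biogenesis. Of the G1/S genes, 20 of 32 tested members fell and 12 were not called (27 lower adjusted over the list alone; camera adjusted p = 1.96e-07, or 0.469 with an estimated correlation). The transcription factor E2f2 fell (log2FC -1.68, adjusted p = 0.0056), as did cyclin E2 (Ccne2, log2FC -0.80, adjusted p = 0.00392). The replication clamp Pcna fell from 813 ± 17.2 to 454 ± 49.4 FPKM (log2FC -0.85, adjusted p = 0.00355). Of the G2/M genes, 13 of 30 tested members fell and 17 were not called (18 lower adjusted over the list alone; camera adjusted p = 1.55e-05, or 0.577 with an estimated correlation). Cyclin A2 (Ccna2, log2FC -0.89, adjusted p = 0.0119) and the topoisomerase Top2a (log2FC -0.69, adjusted p = 0.0158) were among them. Of the ribosome biogenesis genes, which are known MYC targets, 26 of 36 tested members fell and 10 were not called (31 lower adjusted over the list alone; camera adjusted p = 7.24e-10, or 0.469 with an estimated correlation). Ppan (log2FC -1.12, adjusted p = 0.00176), the spermidine synthase Srm (log2FC -1.11, adjusted p = 0.00227) and the nucleolar protein Nop56 (log2FC -1.02, adjusted p = 0.00251) were examples. Of the oxidative phosphorylation genes, 2 of 71 tested members rose, 23 fell and 46 were not called (camera adjusted p = 0.000166, or 0.469 with an estimated correlation). Changes were small, as for Ndufc1 of complex I (log2FC -0.59, adjusted p = 0.00662). Of the cholesterol synthesis genes, 8 of 24 tested members fell and 16 were not called (camera adjusted p = 0.00186, or 0.609 with an estimated correlation), Pmvk the most (log2FC -1.10, adjusted p = 0.00412). Among cyclins and CDK inhibitors, 4 of 15 tested members rose, 4 fell and 7 were not called (camera adjusted p = 0.905). Cyclin D3 (Ccnd3), the main D cyclin of pre-B cells, fell from 1119 ± 114 to 278 ± 123 FPKM (log2FC -2.13, adjusted p = 0.01). Its kinase partner Cdk6 rose from 24 ± 3.34 to 120.0 ± 46.1 FPKM (log2FC 2.21, adjusted p = 0.00481). Of the glycolysis genes, 4 of 23 tested members fell and 19 were not called (camera adjusted p = 0.0431, or 0.588 with an estimated correlation). The integrated stress response was called lower too (3 higher and 9 lower of 22 tested; camera adjusted p = 0.0492, or 0.577 with an estimated correlation). Quantile normalization ended both calls (camera adjusted p = 0.134 and 0.134), as did median centring (0.0885 and 0.0885). The stress response was not called without library 244 (0.0706) or with voom (0.0514) either.

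Many genes of immune signalling and of lysosomes were higher. Of the NF-κB target genes, 11 of 21 tested members rose and 10 were not called (12 higher adjusted over the list alone; camera adjusted p = 0.000295, or 0.577 with an estimated correlation). The adaptor Traf1 led (log2FC 4.59, adjusted p = 0.00382), followed by the chemokines Ccl3 (log2FC 3.86, adjusted p = 0.00458) and Ccl4 (log2FC 3.44, adjusted p = 0.0169), which NK cells also make. Of the interferon response genes, 11 of 25 tested members rose, 1 fell and 13 were not called (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00164, or 0.469 with an estimated correlation). The regulator Irf7 (log2FC 2.61, adjusted p = 0.0012) and the GTPase Igtp (log2FC 1.95, adjusted p = 0.00124) rose. Of the lysosome and autophagy genes, 18 of 35 tested members rose, 4 fell and 13 were not called (20 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.00236, or 0.469 with an estimated correlation). The autophagy receptor Optn stood at 28.4 ± 5.37 against 3.17 ± 0.0555 FPKM (log2FC 2.80, adjusted p = 0.000506), while Tfeb, the transcription factor of lysosomal genes, fell (log2FC -1.22, adjusted p = 0.0067). These lists rose in the same libraries as the NK/ILC, T cell and myeloid markers. Of the BCL2 family, 5 of 15 tested members rose and 10 were not called (camera adjusted p = 0.156), and Bcl2 itself rose from 13.2 ± 3.7 to 62.4 ± 7.05 FPKM (log2FC 2.19, adjusted p = 0.00229). The remaining lists were not called. These were p53 targets (4 higher and 2 lower of 19 tested; camera adjusted p = 0.408), FOXO targets (2 higher and 3 lower of 19 tested; camera adjusted p = 0.567) and TCA cycle (2 higher and 7 lower of 27 tested; camera adjusted p = 0.301). They also held endoplasmic reticulum chaperones (3 higher and 5 lower of 20 tested; camera adjusted p = 0.317) and glycogen metabolism (3 higher and 2 lower of 16 tested; camera adjusted p = 0.317).

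Of 32 lists tested with camera at its preset correlation, 20 were called, and 0 were called with an estimated correlation. Of all genes called, 51.3% were higher, against 40.8% after quantile normalization and 37.0% after median centring. Median centring moved the median log2FC of all tested genes from -0.02 to -0.14. Leaving out 1 library moved the counts most for sorted control 251 (1012 higher, 523 lower), sorted control 242 (1224 and 750), sorted control 249 (1248 and 756) and library 262 (968 and 1093).

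The second comparison asked what overnight GSK3 inhibition does in unsorted wildtype precursors. Nkd1, Axin2 and Apcdd1, feedback genes of the WNT pathway, rose in every inhibitor library, surrogate light chain and other pre-B cell genes fell, and some T lineage genes rose. Few NK/ILC and myeloid markers were called in the fit without the pairing. Nkd1 (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884) rose from 1.35 ± 0.162 to 122 ± 25.3 FPKM (mean ± SD, n = 3; log2FC 5.69 ± 0.179 SE, adjusted p = 6.38e-05) and Axin2 from 2.78 ± 0.264 to 57.2 ± 13.1 (log2FC 3.92 ± 0.183 SE, adjusted p = 0.000177). Spib fell from 519 ± 54.8 to 26.4 ± 14.4 FPKM (log2FC -4.38 ± 0.367 SE, adjusted p = 0.000784). With limma, 1074 genes were higher and 1218 lower of 12685 tested, of which 553 and 593 changed at least 2-fold. With the library number as a block, which the pairing of the libraries allows, 1783 were higher and 2033 lower.

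Of the WNT target genes, 9 of 14 tested members rose, 2 fell and 3 were not called (9 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000153, or 0.802 with an estimated correlation). Kremen1, which encodes a receptor for the WNT antagonist DKK1, rose from 6.97 ± 0.796 to 198 ± 54.1 FPKM (log2FC 4.61 ± 0.22 SE, adjusted p = 0.000183). Apcdd1 rose from 0.18 ± 0.105 to 25.2 ± 4.17 (log2FC 4.46 ± 0.187 SE, adjusted p = 0.000102) and Tcf7 from 12 ± 9.56 to 153 ± 29.1 (log2FC 3.84 ± 0.538 SE, adjusted p = 0.00511). Rnf43 was too low to be tested here (group means of 2 ± 2.79 and 1.49 ± 1.65 FPKM). Myc fell from 65.1 ± 21 to 11.8 ± 1.65 FPKM (log2FC -2.33 ± 0.235 SE, adjusted p = 0.00142), although it is a WNT target in other tissues. Lef1 (log2FC 0.11, adjusted p = 0.791), Ctnnb1 (log2FC -0.08, adjusted p = 0.595), Gsk3a (log2FC 0.19, adjusted p = 0.268) and Gsk3b (log2FC -0.02, adjusted p = 0.935) were not called. Of the pathway components, 1 of 23 tested members rose, 4 fell and 18 were not called (camera adjusted p = 0.709), and Bcl9 fell (log2FC -1.04, adjusted p = 0.00536). The genes with the largest rises were the MHC class I-like H2-Q2, from 0.207 ± 0.123 to 121 ± 16.4 FPKM (log2FC 6.66, adjusted p = 3.77e-05), Ak8 (log2FC 6.42, adjusted p = 0.000505), the membrane metalloprotease Mmp15 (log2FC 5.88, adjusted p = 6.38e-05) and the kinase gene Mylk4 (log2FC 5.78, adjusted p = 7.72e-05). H2-Q1, a neighbour of H2-Q2 (log2FC 5.72, adjusted p = 0.00031), Nkd1 and Phlda1 (log2FC 5.63, adjusted p = 0.000132) followed. The split of reads within the H2-Q family of similar genes is uncertain. The retinaldehyde dehydrogenase Aldh1a3 (log2FC 5.50, adjusted p = 0.000109), Tex14 (log2FC 5.45, adjusted p = 0.000102) and the transporter Slc16a5 (log2FC 5.38, adjusted p = 0.000311) rose too.

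Many pre-B cell genes fell. Of the pre-BCR and pro/pre-B genes, 1 of 28 tested members rose, 16 fell and 11 were not called (2 higher and 16 lower adjusted over the list alone; camera adjusted p = 7.74e-06, or 0.802 with an estimated correlation). The surrogate light chain genes fell in step. Vpreb1 fell from 1945 ± 259 to 131 ± 13.8 FPKM (log2FC -3.88 ± 0.136 SE, adjusted p = 7.72e-05). Vpreb2 fell from 1631 ± 159 to 78.3 ± 14.9 FPKM (log2FC -4.38 ± 0.161 SE, adjusted p = 7.72e-05) and Igll1 from 1188 ± 143 to 102 ± 11.7 (log2FC -3.53 ± 0.131 SE, adjusted p = 7.72e-05). Of the B lineage transcription factors, 6 of 26 tested members rose, 8 fell and 12 were not called (camera adjusted p = 0.168; with the block camera adjusted p = 0.0446, or 0.873 with an estimated correlation). Pax5 fell from 552 ± 168 to 101 ± 23.8 FPKM (log2FC -2.43, adjusted p = 0.00175) and Bcl11a from 53.2 ± 10.7 to 4.42 ± 1.38 (log2FC -3.33, adjusted p = 0.000492). Lmo2 rose to 165 ± 13.7 (log2FC 3.46, adjusted p = 0.00168). Of the immature and mature B cell genes, 2 of 22 tested members rose, 6 fell and 14 were not called (camera adjusted p = 0.0931). With the block the counts were 2 higher and 15 lower of 22 tested (camera adjusted p = 0.000322, or 0.676 with an estimated correlation). Of the V(D)J recombination genes, 2 of 12 tested members rose, 3 fell and 7 were not called (camera adjusted p = 0.709). The recombinase genes Rag1 (log2FC -2.54, adjusted p = 0.00602) and Rag2 (log2FC -2.14, adjusted p = 0.0237) fell. Dntt, the terminal transferase of pro-B cells, rose from 235 ± 45 to 888 ± 77.6 FPKM (log2FC 1.93, adjusted p = 0.000707). Rag1 and Rag2 are also among the FOXO targets, of which 3 of 19 tested members rose, 8 fell and 8 were not called (camera adjusted p = 0.193). Plasma cell genes went both ways (5 higher and 4 lower of 15 tested; camera adjusted p = 0.709), and Prdm1 rose from 1.05 ± 0.631 to 32.3 ± 8.78 FPKM (log2FC 4.04, adjusted p = 0.000674). The largest falls also included the guanine exchange factor Fgd2 (log2FC -4.88, adjusted p = 0.000877), Syndig1l (log2FC -4.56, adjusted p = 0.00324), the Notch effector Heyl (log2FC -4.50, adjusted p = 0.000402) and the cytochrome Cyp4f18 (log2FC -4.41, adjusted p = 0.00032). Vat1l (log2FC -4.31, adjusted p = 0.000227), Sh2d5 (log2FC -4.13, adjusted p = 0.000231), the ATP receptor P2rx3 (log2FC -4.05, adjusted p = 0.0039) and Tmprss3 (log2FC -3.98, adjusted p = 0.00114) followed.

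**Figure D3:**
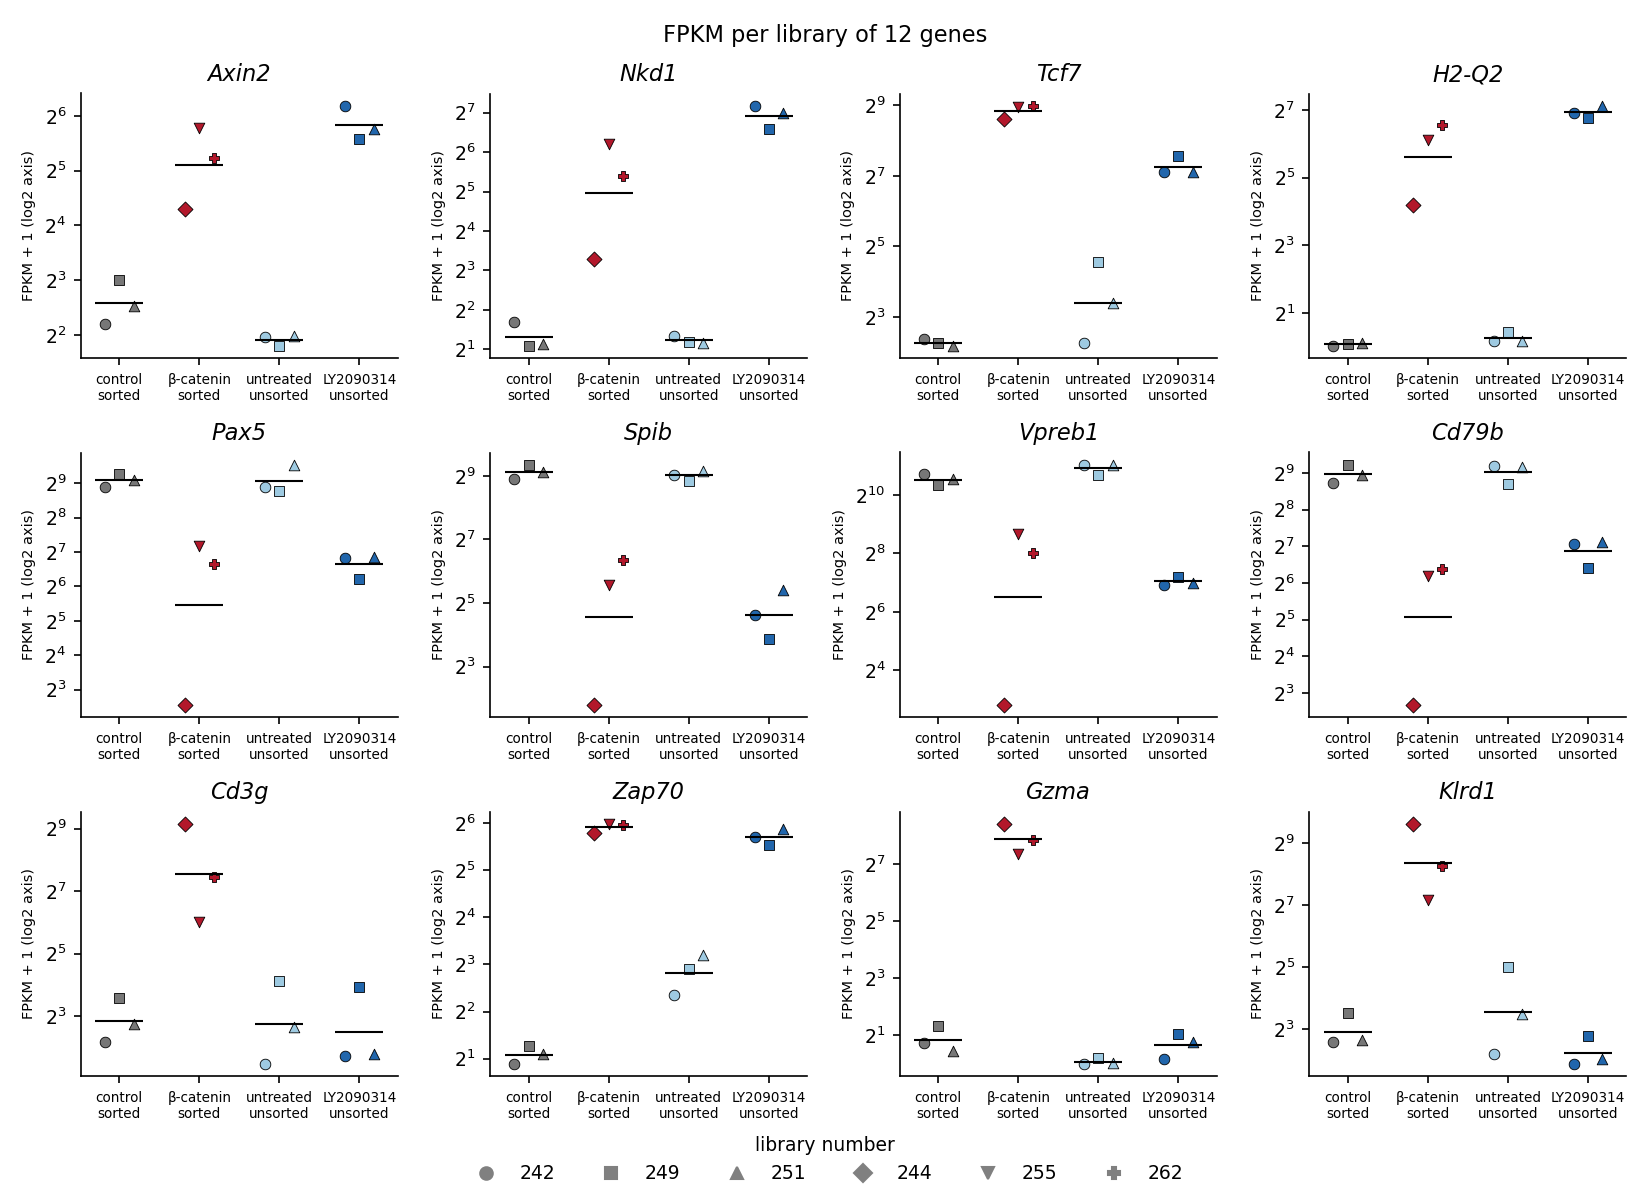
FPKM + 1 (log2 axes) of 12 genes in each library, with 1 symbol per library number and a line at the mean of the log2 values of each group. Axin2, Nkd1, Tcf7, H2-Q2 and Zap70 were higher and Spib, Vpreb1 and Cd79b lower in every β-catenin and inhibitor library than in every library of their control groups, whereas Gzma and Klrd1 stood apart from the controls in the β-catenin libraries only.

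Some T cell markers rose in this comparison, and few markers of other cell types were called. The difference between these lists was not tested. Of the T cell markers, 5 of 10 tested members rose, 1 fell and 4 were not called (camera adjusted p = 0.0355, or 0.802 with an estimated correlation). Cd8b1 rose from 0.633 ± 0.903 to 23.3 ± 3.47 FPKM (log2FC 4.02 ± 0.374 SE, adjusted p = 0.00107) and Zap70 from 6.25 ± 2.03 to 51.6 ± 6.22 (log2FC 2.89 ± 0.229 SE, adjusted p = 0.000674). The costimulatory receptor Cd28 rose from 1.98 ± 2.31 to 12.1 ± 7.93 FPKM (log2FC 2.25, adjusted p = 0.0484). Cd3g was not called (group means of 7.78 ± 7.6 and 6.38 ± 6.93 FPKM). Of the Notch and T lineage list, 6 of 20 tested members rose, 3 fell and 11 were not called (camera adjusted p = 0.273), and the Notch target Hes1 was among those that fell (log2FC -2.61, adjusted p = 0.000366). Of 11 tested NK/ILC markers, 1 was called, a fall of Klrb1c (log2FC -2.17, adjusted p = 0.0494). Of 15 monocyte and macrophage markers limma called 0 (0 higher and 0 lower at an unadjusted p under 0.05, and 0 with voom). Single genes were called among the neutrophil (Ly6g, log2FC 3.58, adjusted p = 0.0362), mast cell (Il5ra, log2FC 2.94, adjusted p = 0.00107) and erythroid markers (Car2, log2FC -1.45, adjusted p = 0.00209). None of these lists was called (camera adjusted p = 0.853, 0.935 and 0.853). These fits leave out the pairing by number. The summed FPKM of mast cell markers was lower with the inhibitor for every number. In the order 242, 249 and 251 it was 168.7, 1223 and 211.5 against 259.4, 2215 and 442.7. That of monocyte markers was higher for every number (144.9, 4657 and 302.4 against 143, 3430 and 290.7). NK/ILC and neutrophil sums went both ways, and none of these sums was tested. Of 5 dendritic cell markers limma called 0 (2 higher and 1 lower at an unadjusted p under 0.05, and 0 with voom). The summed FPKM of that list was lower for every number (9.313, 44.18 and 10.49 against 10.74, 74.1 and 18.63), which was not tested either. Of the stem and progenitor markers, 1 of 8 tested members rose, 1 fell and 6 were not called (camera adjusted p = 0.733). Both libraries numbered 249 carried 7664 and 7575 summed FPKM of neutrophil markers. Without them 1111 genes were higher and 1254 lower, and 1694 of the 2292 genes were called again. There 11679 genes were tested. A gene below 1 FPKM in both remaining untreated libraries, such as H2-Q2 or Apcdd1, could not pass the filter. Genes left untested count among those not called again.

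Some growth genes fell with the inhibitor, and mitotic genes were not called, in the fit without the pairing by number. With the number as a block 1783 genes were higher and 2033 lower, and camera called 10 lists in place of 8. Lists and genes not called in the fit without the pairing are thus not shown to be unchanged. Of the G1/S genes, 2 of 32 tested members rose, 13 fell and 17 were not called (2 higher and 20 lower adjusted over the list alone; camera adjusted p = 7.74e-06, or 0.98 with an estimated correlation). Ccne2 (log2FC -1.17, adjusted p = 0.0164), E2f2 (log2FC -1.14, adjusted p = 0.0264) and the thymidine kinase Tk1 (log2FC -1.12, adjusted p = 0.00191) fell. Of 30 G2/M genes limma called 0 (1 higher and 1 lower at an unadjusted p under 0.05, and 0 with voom). Of the ribosome biogenesis genes, 10 of 36 tested members fell and 26 were not called (18 lower adjusted over the list alone; camera adjusted p = 7.74e-06, or 0.98 with an estimated correlation). Srm (log2FC -1.20, adjusted p = 0.00929) and nucleophosmin (Npm1, log2FC -0.86, adjusted p = 0.00506) fell. Of the oxidative phosphorylation genes, 16 of 71 tested members fell and 55 were not called (19 lower adjusted over the list alone; camera adjusted p = 8.63e-08, or 0.802 with an estimated correlation), Ndufa12 the most (log2FC -0.81, adjusted p = 0.0354). Among cyclins and CDK inhibitors, 2 of 15 tested members rose, 4 fell and 9 were not called (camera adjusted p = 0.733). Ccnd3 fell from 1322 ± 178 to 201 ± 60.4 FPKM (log2FC -2.74, adjusted p = 0.00071) and Cdk6 rose from 28 ± 4.78 to 113 ± 15 (log2FC 1.98, adjusted p = 0.000674). Of the lysosome and autophagy genes, 4 of 36 tested members rose, 2 fell and 30 were not called (camera adjusted p = 0.0123, or 0.98 with an estimated correlation). Optn (log2FC 3.13, adjusted p = 0.000712) and the lysosomal membrane gene Lamp2 (log2FC 2.31, adjusted p = 0.000947) rose and Tfeb fell (log2FC -1.11, adjusted p = 0.0034). The integrated stress response list was called higher although 2 of 25 tested members rose, 2 fell and 21 were not called (camera adjusted p = 0.0123, or 0.98 with an estimated correlation). With the block, 15 higher and 3 lower of 25 tested were called. The BCL2 family (3 higher and 2 lower of 15 tested; camera adjusted p = 0.824) held a fall of the proapoptotic Bmf (log2FC -2.51, adjusted p = 0.0097) and rises of Pmaip1 (Noxa; log2FC 1.72, adjusted p = 0.0025) and Bcl2 (log2FC 1.47, adjusted p = 0.0101). The other lists were not called. These were p53 targets (1 higher and 3 lower of 20 tested; camera adjusted p = 0.876), glycolysis (3 higher and 1 lower of 25 tested; camera adjusted p = 0.709), TCA cycle (2 higher and 5 lower of 27 tested; camera adjusted p = 0.709) and chaperones (2 higher and 6 lower of 20 tested; camera adjusted p = 0.397). They also held cholesterol synthesis (2 higher and 0 lower of 24 tested; camera adjusted p = 0.853), glycogen metabolism (1 higher and 1 lower of 16 tested; camera adjusted p = 0.733), NF-κB targets (0 higher and 2 lower of 21 tested; camera adjusted p = 0.935) and interferon response (1 higher and 1 lower of 20 tested; camera adjusted p = 0.709).

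At the preset correlation camera called 8 of 33 lists, and 0 with an estimated correlation. Leaving out inhibitor library 242 gave 433 higher and 590 lower genes, inhibitor library 251 475 and 672, untreated library 242 584 and 503, untreated library 251 577 and 500, and untreated library 249 779 lower.

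Whether both manipulations move the same genes was asked over the 12059 genes tested in both, from comparisons that share no library. Called genes overlapped in direction. Of them 461 genes were higher in both, against 174.9 for independent lists (2.64 times; Fisher's exact test across genes, p = 4.63e-108). Lower in both were 645, against 212.4 (3.04 times, exact p = 3.6e-202). Genes are not independent replicates, so these p-values describe the lists only. The number called in opposite directions was 50 (higher with β-catenin, lower with the inhibitor) and 21. Across genes the log2 fold changes had a Pearson r of 0.48 and a Spearman rho of 0.43, and 65.6% had the same sign. Ak8, H2-Q2, Apcdd1, Nkd1, Axin2, Tcf7, Cd8b1, Zap70 and Prdm1 were among the genes that rose in both, and Spib, Vpreb2, Blk, Ccnd3, Hes1, Tfeb and Myc among those that fell in both. H2-Q2 stood at 59.8 ± 39 FPKM in the β-catenin libraries against 0.0515 ± 0.0314 in their controls (log2FC 5.55, adjusted p = 0.00286). Without library 244 and the unsorted libraries numbered 249, 671 genes were higher and 711 lower in both. With the block in the inhibitor fit, 735 genes were higher in both. Without the filter, over 23015 genes tested in both, fewer genes were shared, with 283 higher and 363 lower in both. Relative to independent lists the overlap was larger there, at 4.29 times for higher and 5.86 times for lower genes.

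**Figure D4:**
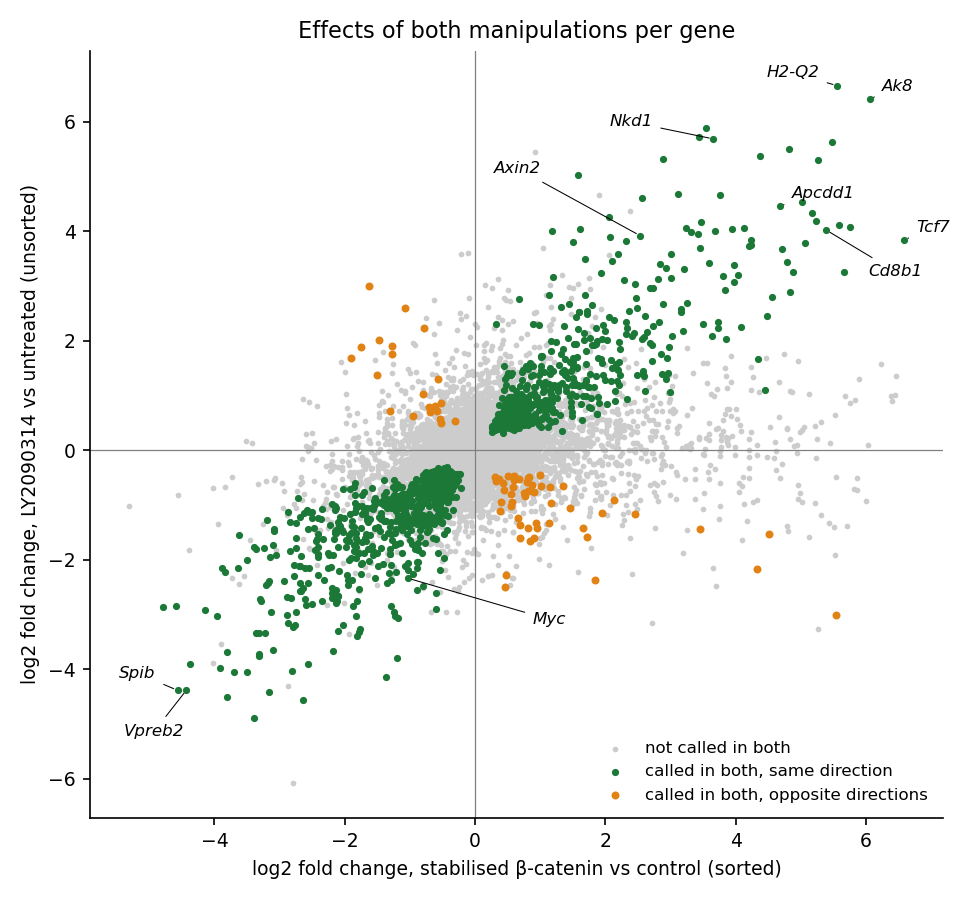
Log2 fold change of FPKM + 1 of each gene tested in both comparisons, with stabilised β-catenin against sorted control on the x axis and LY2090314 against untreated on the y axis. The 1106 genes called in both in the same direction (green) include Tcf7 (6.58 and 3.84) and Nkd1 (3.66 and 5.69), and 71 genes were called in opposite directions (orange).

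The difference between both effects was tested directly in a model of all 12 libraries, in which it also carries the sort and the overnight culture. Xcl1, Gzmc, Ccl5, Il2rb and Ctsw had the greater rise with stabilised β-catenin, and Pon3, Tex14, Mylk4 and Npl had the greater rise with the inhibitor. Xcl1, a chemokine of NK and CD8 T cells, had the largest difference (log2FC 8.54 ± 1.16 SE, adjusted p = 0.00326). It stood at 340.4 ± 287 FPKM in the β-catenin, 5.01 ± 2.48 in the sorted control, 16.3 ± 18.1 in the untreated and 0.768 ± 1.29 in the inhibitor libraries. The granzyme Gzmc (log2FC 8.52 ± 1.68 SE, adjusted p = 0.0157), the chemokine Ccl5 (log2FC 7.43 ± 1.16 SE, adjusted p = 0.00588), Il2rb (log2FC 7.09 ± 1.25 SE, adjusted p = 0.0103) and the cathepsin Ctsw (log2FC 6.91 ± 1.04 SE, adjusted p = 0.00491) followed. A negative difference means that the inhibitor had the higher effect. The esterase Pon3 rose from 10.5 ± 1.91 to 90.5 ± 7.3 FPKM with the inhibitor and fell from 10.7 ± 0.938 to 3.07 ± 2.12 with β-catenin (log2FC -4.64 ± 0.395 SE, adjusted p = 0.00035 for the difference). Tex14 (log2FC -4.53, adjusted p = 0.00762), Mylk4 (log2FC -4.01, adjusted p = 0.00364) and the sialic acid lyase Npl (log2FC -3.80, adjusted p = 0.00192) rose more with the inhibitor. Fcrla fell more with β-catenin (log2FC -4.29, adjusted p = 0.0119). With voom the differences of Xcl1 (adjusted p = 0.1), Tex14 (0.0673), Fcrla (0.0674) and Mylk4 (0.267) were not called. Tcf7 rose more with β-catenin (log2FC 2.74, adjusted p = 0.0241). This call was lost without the filter (0.0538), with voom (0.0516), and without sorted control 242 (0.0539), 249 (0.0591) or 251 (0.0648). It was also lost without library 262 (0.0635), untreated library 251 (0.0547), inhibitor library 242 (0.0615) or inhibitor library 251 (0.0626). Axin2 (log2FC -1.39, adjusted p = 0.0928) and Myc (log2FC 1.30, adjusted p = 0.0706) were not called, except without library 255 (adjusted p = 0.0266 and 0.046). Lef1 (log2FC -1.44, adjusted p = 0.301), Ctnnb1 (log2FC 0.16, adjusted p = 0.61), Gsk3a (log2FC 0.11, adjusted p = 0.601) and Gsk3b (log2FC 0.07, adjusted p = 0.826) were not called. With limma, 841 of 13861 genes had the higher and 423 the lower effect with β-catenin. Of these differences 66.5% were positive, against 55.3% after quantile normalization and 51.9% after median centring.

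Marker and process lists were tested on the same difference. Of the NK/ILC markers, 13 of 15 tested had the greater effect with β-catenin (camera adjusted p = 1.75e-12, or 0.37 with an estimated correlation). So did 6 of 13 T cell markers (camera adjusted p = 6.54e-06, or 0.268 with an estimated correlation), the kinase gene Lck among them (log2FC 2.53, adjusted p = 6.89e-05). The Notch and T lineage list followed with 11 of 24 (camera adjusted p = 1.88e-08, or 0.268 with an estimated correlation) and the dendritic cell markers with 4 of 10 (camera adjusted p = 0.000113, or 0.37 with an estimated correlation). NF-κB targets (2 of 21; camera adjusted p = 8.92e-05, or 0.853 with an estimated correlation) and interferon response genes (3 of 27; camera adjusted p = 0.000505, or 0.853 with an estimated correlation) were called in this direction with few single genes. The BCL2 family (1 of 17; camera adjusted p = 0.0394, or 0.37 with an estimated correlation) was not called without library 244 and the unsorted libraries numbered 249 (adjusted p = 0.131). In the other direction camera called the integrated stress response with 7 of 25 genes (camera adjusted p = 0.000377, or 0.37 with an estimated correlation). Its genes Asns, an asparagine synthetase (log2FC -3.43, adjusted p = 0.0145), and Chac1 (log2FC -3.42, adjusted p = 0.0216) fell with β-catenin relative to the inhibitor. G2/M genes (1 of 30; camera adjusted p = 3.19e-06, or 0.853 with an estimated correlation) and cholesterol synthesis (2 of 24; camera adjusted p = 0.000256, or 0.853 with an estimated correlation) were called likewise. Glycolysis was called with 2 of 26 genes (camera adjusted p = 0.0362, or 0.959 with an estimated correlation), and not after quantile normalization (adjusted p = 0.117) or median centring (0.0586). The WNT target list was not called (3 higher and 2 lower of 18 tested; camera adjusted p = 0.565), and Rnf43 had the greater effect with β-catenin (log2FC 4.20, adjusted p = 0.0209). Without library 244 and the unsorted libraries numbered 249 it was called lower with β-catenin (camera adjusted p = 0.0284, or 0.307 with an estimated correlation). The counts moved to 1277 and 670 genes without those 3 libraries, to 550 and 258 without the filter and to 383 and 231 with voom. Without sorted control 242 they were 397 and 201, without sorted control 249 364 and 152, and without sorted control 251 331 and 148. Without library 255 they were 1130 and 696, and without library 262 298 and 182. Without untreated library 249 they were 480 and 228, and without untreated library 251 457 and 214. Without inhibitor library 242 they were 386 and 165, without inhibitor library 249 1300 and 697, and without inhibitor library 251 418 and 182.

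The last comparison set the sorted controls against the untreated unsorted cultures, to show what the sort and the overnight culture carry. Mast cell genes and single macrophage genes were lower in the sorted controls. Some targets of p53 were higher in the overnight cultures, and of the B lineage transcription factors only Irf8 and Myb were called, both by less than 0.5. Tpsb2, a mast cell tryptase, stood at 10.5 ± 10.8 against 347 ± 349 FPKM (log2FC -5.18, adjusted p = 0.037). The mast cell carboxypeptidase Cpa3 (log2FC -4.89, adjusted p = 0.0277) and the chymase Cma1 (log2FC -4.65, adjusted p = 0.0304) were lower, as were the macrophage genes Gpnmb (log2FC -5.16, adjusted p = 0.0228) and Mmp12 (log2FC -4.14, adjusted p = 0.0247). None of these 5 genes kept its call without the filter, with voom or without any 1 of the sorted controls, the highest adjusted p for Tpsb2 being 0.128 without sorted control 251. Of the mast, basophil and eosinophil markers, 6 of 10 tested members fell and 4 were not called (camera adjusted p = 1.66e-05, or 0.551 with an estimated correlation). Untreated library 249 stood apart here, with summed FPKM of 2215 for mast cell markers against 259 and 443 in untreated libraries 242 and 251. For monocyte markers it had 3430.0 against 143 and 291, and for neutrophil markers 7664 against 44.4 and 482. Without both libraries numbered 249 the mast cell counts were 0 higher and 3 lower of 6 tested (camera adjusted p = 0.00029, or 0.606 with an estimated correlation), and fewer than 5 neutrophil markers were left to test. The monocyte list (camera adjusted p = 0.0691) and the WNT pathway components (0.0831) were not called without them. Of the p53 targets, 8 of 20 tested members fell and 12 were not called (camera adjusted p = 7.45e-10, or 0.551 with an estimated correlation). Phlda3 (log2FC -2.45, adjusted p = 0.00714), Bbc3 (Puma, log2FC -1.72, adjusted p = 0.00761) and Ccng1 (log2FC -1.37, adjusted p = 0.00457) were lower. So were the cell cycle inhibitors Cdkn2a (log2FC -2.59, adjusted p = 0.0013) and Cdkn1a (log2FC -1.16, adjusted p = 0.00364). Of the ribosome biogenesis genes, 9 of 36 tested members rose and 27 were not called (camera adjusted p = 4.45e-08, or 0.551 with an estimated correlation). Of the oxidative phosphorylation genes, 12 of 71 tested members fell and 59 were not called (camera adjusted p = 2.31e-10, or 0.551 with an estimated correlation). Glycolysis (5 of 24; camera adjusted p = 0.000126), cholesterol synthesis (3 of 24; 8.94e-06), G1/S (5 of 32; 2.1e-06), interferon response (3 of 23; 0.006) and WNT pathway components (2 of 24; 0.0234) were called higher. Lysosome and autophagy genes (3 of 35; 0.000121), NK/ILC markers (2 of 10; 0.00142) and pre-BCR genes (3 of 28; 0.0343) were called lower. The monocyte (camera adjusted p = 0.00819) and neutrophil lists (0.00087, and 0.133 with voom) were called lower without a single called gene. Of all these lists none was called with an estimated correlation (adjusted p = 0.551, and 0.603 for the monocyte list). The genes with the largest rises were Tead1 (log2FC 2.69, adjusted p = 0.0134), Stac2 (log2FC 2.51, adjusted p = 0.0289), Mpp3 (log2FC 2.37, adjusted p = 0.00281), Egfl7 (log2FC 2.31, adjusted p = 0.0106) and Lamb2 (log2FC 2.25, adjusted p = 0.0173). Stac2 was not called without the filter (adjusted p = 0.0808), with voom (0.085) or without sorted control 249 (0.0822), sorted control 251 (0.128), untreated library 242 (0.0553) or untreated library 251 (0.0778). Lamb2 was not called without the filter (0.0514) or without sorted control 242 (0.0538), 249 (0.073) or 251 (0.0945), nor was Egfl7 without sorted control 251 (0.0792). Of the WNT target genes limma called 0 of 12 (6 higher and 0 lower at an unadjusted p under 0.05, and 0 with voom; camera adjusted p = 0.0613, but 0.0463 with voom). With limma, 502 of 12513 genes were higher and 537 lower in the sorted controls. These counts rested on few libraries. Without sorted control 251 they were 7 and 16, without sorted control 249 24 and 58, and without sorted control 242 53 and 77. Without untreated library 251 they were 128 and 113, and without both libraries numbered 249 they were 114 and 177.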

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

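The tests of cell mixtures given here were chosen after the results were seen, and the counts over other splits of the libraries were chosen before the data were examined. The test of the difference between both effects, which also carries the sort and the overnight culture, called 841 genes with the higher and 423 with the lower effect of β-catenin. Among the genes named by the rule, the difference was 8.54 for Xcl1, 8.52 for Gzmc, 7.43 for Ccl5, 7.09 for Il2rb and 6.91 for Ctsw (log2 scale). It was -4.64 for Pon3, -4.53 for Tex14, -4.29 for Fcrla, -4.01 for Mylk4 and -3.80 for Npl, and 2.74 for Tcf7. Of 100 drawn pairs of splits, 3 gave as many genes as the real 1264, the real one included, and the highest other gave 3056. All 3 kept the real sorted groups, and draws with both splits other than real gave at most 1. A draw with 1 real effect can thus reach the count, so these draws do not decide whether chance gave the difference.

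The rise of T cell and NK/ILC transcripts in the β-catenin libraries was not carried by library 244 alone, since 14 of 17 tested markers rose without it. A single outside population of fixed makeup was argued against as the supplier of all risen T cell transcripts, because their ratios between libraries 255 and 244 spanned 2.23 on the log2 scale (6 genes, ratios 0.264 to 1.46). The limit for that span was set after the results were seen. Outside cells whose makeup differed between these libraries stayed open. A loss of B cells as the whole reason for the fall of B lineage genes stayed open. Among the B lineage genes that library 244 held below 0.02 of the control level, the changes in libraries 255 and 262 spanned 1.34 (15 genes), and below 0.2 they spanned 2.28 (27 genes), so the span depends on where that bound is set. For the NK/ILC transcripts 1 outside population stayed open (span 1.36, 12 genes, ratios 0.129 to 0.471), and the purity of the B220 sort was not tested. A rise within B lineage cells could not be told apart from it. The inhibitor raised 0 of 11 NK/ILC markers by limma and 5 of 10 T cell markers in other cultures. Those cultures were unsorted, so these counts do not show which cells held the transcripts.

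Xist and Y-linked transcripts together in library 244 were weighed second. Its Xist ratio to sorted control 242, the only other sorted library with abundant Xist, was 0.573. Its mean ratio of Y-linked genes to the male sorted libraries was 0.509. Both argue against a library taken whole from another animal, but they are the values that raised the question and no separate test. Male cells that gained Xist were argued against, because the highest of 4 ratios of Y-linked genes to the male sorted libraries was 0.54. That ratio was of Ddx3y, which in library 244 (19.51 FPKM) still lay above the male untreated library 249 (13.65). Eif2s3y (39.9), Kdm5d (6.684) and Uty (4.712) in library 244 lay below every male library, the lowest of which held 61.71, 12.41 and 6.887. The Xist ratio and the mean Y ratio add up to 1.08, as male and female cells in 1 library could give, and no other biological explanation was tested.

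Myeloid and mast cell transcripts in the unsorted libraries numbered 249 were weighed last. An effect of the inhibitor was argued against, because the summed FPKM of these markers in the untreated library was 0.975 of that in the inhibitor library. Of 37 markers, 35 were higher in both libraries than in the other 4 unsorted ones. Myeloid and mast cells in that culture would dilute B lineage transcripts, and of 54 B lineage genes 30 were the lowest of their group in both libraries and 6 the highest, consistent with such cells. The sums were 12890 and 13230 FPKM there, 420.4 to 1210 in the other unsorted libraries and 190.8 in the sorted control of the same number.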

How the results depend on the processing

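Settings named here as voom or as leaving out 2 or more libraries were chosen after the data were seen. The genes followed through these settings were those named for their fold change or fixed by name. They numbered 26 with β-catenin, 27 with the inhibitor, 17 in the difference and 17 between the control groups. None of them reversed where it was tested, and other named genes were not followed. Higher genes outnumbered lower ones with β-catenin (2387 and 2269), but not after quantile normalization (1993 and 2891) or median centring (1932 and 3291), with a filter of 5 FPKM (1871 and 1934), with voom (2060 and 2092) or without any 1 β-catenin library. Lower genes were the more with the inhibitor (1074 and 1218), but not without any 1 untreated library. Between the control groups (502 and 537) this order turned after quantile normalization (571 and 499), with voom (498 and 454) and without untreated library 242 (491 and 425) or 251 (128 and 113). The β-catenin counts stayed within 1.5 times (1871 to 2402 higher, 1772 to 3291 lower) except for single left-out libraries (968 to 2386 higher, 523 to 2616 lower). With the replicate block, which the pairing allows, the inhibitor counts were 1783 and 2033, and without the filter 810 genes were lower. Left-out libraries gave 433 to 961 and 500 to 1239. The difference of effects moved to 550 and 258 without the filter, where more genes are adjusted for, to 383 and 231 with voom and to 1277 and 670 without library 244 and the unsorted libraries numbered 249. Left-out libraries gave 298 to 1300 and 148 to 697. Sorted controls against untreated gave 150 and 202 without the filter, 298 and 312 with all 12 libraries in the fit and 114 and 177 without the libraries numbered 249. There the block gave 145 and 209, but libraries of the same number were the closest for 242 (r = 0.143) and 249 (0.123) and not for 251 (0.000511), so these numbers are not taken as pairs, although 242 was the only number with abundant Xist in both groups (295.1 and 205.3 FPKM). Left-out libraries gave 7 to 528 and 16 to 557. Genes called in both manipulations were 283 higher and 363 lower without the filter, and 735 higher with the block in the inhibitor fit. With an estimated correlation 0 of 20 and 0 of 8 lists kept their call, and fry called 5 of the inhibitor lists. The block changed no other count over all genes by over 1.5 times. Of the followed genes with a call, 9 of 23 lost it under at least 1 setting with β-catenin and 0 of 23 with the inhibitor. A gene that a setting left untested, such as H2-Q2 without the unsorted libraries numbered 249, does not count here as losing its call. In the difference 5 of 11 lost it, and between the control groups 8 of 10. Left-out libraries shrink a group to 2. A gene at 1 FPKM or more in that group alone then cannot pass the filter, so genes higher in that group are lost. How far this turned the order of higher and lower counts was not tested, and for the other moves the cause was not tested either. Simulated 2-fold changes were called in 46%, 35.4%, 22.7% and 57.1% of genes in these comparisons, with fewer genes changed than the real libraries called. Depth was not varied there, and the libraries of a group differed beyond sampling noise (mean chi-square per gene 19.6 to 535.6), so the share that depth limits was not tested. The count-based fits planned for a table of raw counts were not run, since the table holds FPKM.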

Other observations

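Antigen receptor segments were summed by class. The summed FPKM of T cell receptor joining segments was 2173 ± 709 in the β-catenin libraries against 398 ± 116 in their controls (mean ± SD, n = 3), and that of the T cell receptor constant genes 1317 ± 301 against 405 ± 116. T cell receptor variable segments reached 218 ± 23.1 against 39.8 ± 7.05, while immunoglobulin variable segments stood at 125 ± 75.1 against 654 ± 325 and the constant genes at 761 ± 457 against 2189 ± 722. Immunoglobulin joining segments stood at 185, 1408 and 1451 in libraries 244, 255 and 262 (1015 ± 719) against 1243 ± 451, so they were above the control mean in 2 of the 3 libraries. With the inhibitor the T cell receptor variable segments stood at 106 ± 26.7 against 60.7 ± 4.46, the immunoglobulin joining segments at 2304 ± 629.6 against 1270.0 ± 495 and the immunoglobulin variable segments at 612 ± 414 against 447 ± 127. The last rested on number 242 (1087 against 592), as the sums were 330.1 against 362 for 249 and 417 against 386 for 251. These sums were not tested.

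Hsd17b7, a gene of cholesterol synthesis, was among the 71 genes called in opposite directions. It fell with β-catenin (log2FC -0.95, adjusted p = 0.0174) and rose with the inhibitor (log2FC 0.62, adjusted p = 0.045). Spn (CD43), a sialoglycoprotein of early B cells and T cells, rose with β-catenin (log2FC 0.77, adjusted p = 0.0118) and fell with the inhibitor (log2FC -0.83, adjusted p = 0.0252). These genes were picked after the results were seen.

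The shared WNT target response was tested after the results were seen, while the counts over other splits of the libraries were fixed in advance. Of the 11 WNT targets called with the inhibitor, 10 were called in the same direction in the β-catenin libraries, with Myc among them as a fall. Over all genes tested in both, 461 of 1006 called higher and 645 of 1191 called lower with the inhibitor did the same. The prediction of a shared WNT target response was thus met, but many genes outside the list meet it too. The difference between these shares was not tested. Genes called in both in the same direction numbered 1106, against at most 0 in the other drawn pairs of splits (1 of 100 as large, the real one). No other split of either comparison called a gene with limma, which fixes these overlaps at 0, so the draws do not decide whether chance gave the sharing. For the single comparisons the splits are too few for a share under 0.05 (1 of 10 each). The real β-catenin split called 4656 genes and the others at most 0 with limma (up to 307 at an unadjusted p under 0.05), and between the control groups these were 1039 and 0 (up to 518). With the inhibitor the real split called 2292 genes, and the other splits that part all 3 pairs called 0, as did the rest (up to 1137 at an unadjusted p under 0.05). For the lists the splits are also too few, with 20 called in the β-catenin split and at most 19 in another. With the inhibitor 8 lists were called, 7 of the 10 splits gave as many, and the highest other gave 20.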
